A study of Mus musculus with 2 samples.

How the data were processed

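Dendritic cells that had taken up fluorescent house dust mite extract were sorted from the mediastinal lymph node of mice 1 day after the extract was given through the airway. The mice were mixed bone marrow chimeras, so WT and MARCH1 KO cells developed side by side in the same hosts. Each genotype gave 1 single-cell RNA library made with a droplet 3′ kit. Per the labels' protocols, B cells, T cells and neutrophils were first depleted with magnetic beads and live single cells positive for CD11c, MHC class II and the extract were then sorted.

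The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. The authors made these counts with Cell Ranger 3.0.2 per the series' design text, and the submitters' processing notes name Cell Ranger, Seurat and the GRCm38 build. The barcodes are those that the counting software kept, and no cell type annotation was used here. Gene positions were taken from the GENCODE gene models for GRCm38, in which 27645 of the 27998 genes were found by identifier (98.7%).

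Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. This left 1710 of 2441 WT barcodes and 442 of 681 MARCH1 KO barcodes, and most of the others exceeded the mitochondrial limit (686 WT, 227 MARCH1 KO). Scrublet, run in each library through scanpy 1.11.5, called 12 WT and 13 MARCH1 KO cells doublets. They stayed in unless stated. The kept cells held 16804183 UMIs in WT and 6116259 in MARCH1 KO.

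For clustering, counts were scaled to 10000 per cell and log transformed, 2000 variable genes were taken without March1, ribosomal, mitochondrial and antigen receptor genes, and 30 principal components and 15 neighbours gave a shared-neighbour graph for Leiden clustering at resolution 0.8 (leidenalg 0.10.2). Leiden clustering depends on its random start. A first look at the data with 1 start had landed on a partition of 7 clusters. Of 50 starts, 48 gave 8 clusters and 2 gave 7, and the 7-cluster partitions had the lower quality (at most 7389 against 7480 for the best). The partition of highest quality among the 50 starts was therefore used for every clustering. This rule uses no comparison between the libraries, but it was set after both partitions had been seen. The median adjusted Rand index of the 50 starts to the partition used was 0.941 and the lowest 0.699.

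Clusters were named only from marker genes fixed before the data were examined. A name needed at least 3 markers of a class at 10 CPM and 1.5-fold above the other cells, more than for any other class, no larger number of another class's markers among the 10 leading genes, and, in clusters of low depth, a marker of the class among those 10. These thresholds were chosen after seeing the data. Clusters without a class are given by number, and clusters were compared by number.

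UMIs were summed per library and scaled to counts per mega-UMI of the library (CPM), and ratios of MARCH1 KO to WT are log2 values of CPM plus a pseudocount of 10. With 1 library per genotype there are no replicates, so no test was run and no p-value is given. Ratios carry exact conditional 95% intervals, sums exact Poisson intervals and shares exact binomial intervals. All of these cover counting error only and not the difference between animals, sorts or library preparations. The intervals of ratios and sums treat UMIs as independent, so they also leave out variation between cells of a library.

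The named genes follow a rule of size fixed before the data were examined. Over all kept cells they are the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in either library and a UMI in at least 5% of cells of the library where they are higher. Within clusters of at least 50 cells in each library they are the 10 highest and 10 lowest. Ribosomal, mitochondrial, unnamed, haemoglobin, antigen receptor, Xist and Y-linked genes and March1 were left out of the ranking. A small set of genes and the 4 members of each of 24 fixed gene lists with the largest difference were named as well. Genes that lead a cluster were not reported as results within it, and a few of the genes these rules name are not reported here. For each list, members of at least 10 CPM were used, and the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. Members were counted as 1.5-fold apart on the log2 ratio with its pseudocount.

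The ratio and list steps were tested on simulated counts for the comparison over all kept cells, with 200 of 27998 genes changed. Median recovered folds were 1.46 for 1.5, 1.89 for 2 and 2.73 for 3, and 95.5% of the intervals held the true ratio. The simulated sums were Poisson draws from a shared profile, without cells, so they leave out variation between cells. The share of intervals is therefore a check of the calculation only.

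Alternatives fixed beforehand were other cell filters, removal of called doublets, CPM without ribosomal and mitochondrial genes, centring on the median, equal weight per cell, thinning each cell to 3000 UMIs, a pseudocount of 1, reweighting to the WT mix of clusters, resolutions 0.4 and 1.5, MARCH1 KO cells placed by their WT neighbours, and other expression floors. Chosen after seeing the data were leaving out the cell with most UMIs of a gene in each library, clustering without genes 1.5-fold apart between the libraries, and pooling clusters 2 and 3 or 1 and 4.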

Results

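Single-cell 3′ RNA profiles were collected from dendritic cells that carried inhaled house dust mite allergen to the draining lymph node, from 1 WT and 1 MARCH1 KO library. MARCH1 is a membrane ubiquitin ligase known to mark MHC class II and CD86 proteins for turnover, and the comparison asks which transcripts differ in allergen-bearing cells that lack it. The WT library held 2441 barcodes and 18400257 UMIs, and the MARCH1 KO library 681 barcodes and 6894121 UMIs. Barcode numbers, median UMIs (7651 and 6309) and median genes (2004 and 1774) equalled those in the design text. Kept cells were deeper in MARCH1 KO, with a median of 15247 UMIs against 10557 in WT. Neither genotype had a replicate library, so each difference below is between these libraries.

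March1 (ENSMUSG00000036469, chromosome 8, 65617900 to 66471637, GRCm38) was close to absent in both libraries. It had 15 UMIs in WT (0.893 CPM, 95% Poisson interval 8.40 to 24.7 UMIs) and 7 in MARCH1 KO (1.14 CPM, 2.81 to 14.4 UMIs), a ratio of 1.28 (0.442 to 3.34). The depth is too low to check the genotype, and 3′ reads can also lie outside a deleted part.

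The kept cells formed 8 clusters. Clusters 1 to 4 held most of them, 78.8% in WT and 73.5% in MARCH1 KO, and expressed Ccr7, the receptor for lymph node homing, and Fscn1, an actin-bundling protein of mature dendritic cells. Clusters 2 and 3 had more Irf8, a transcription factor of type 1 conventional dendritic cells, at 824 and 853 CPM. Clusters 1 and 4 had 190 and 325 CPM of Irf8 and more Sirpa, a marker of type 2 cells. Cluster 2 met the rule for a cDC1-like name, and clusters 1, 3 and 4 stayed unnamed. Fabp4 and Clu led cluster 1, Il12b and Cd81 cluster 3, and Cd82, Cxcl1, Ccl17 and Ccl22 cluster 4. Cluster 5 had high Malat1, a nuclear RNA, and a median mitochondrial share of 7.8% in WT, and stayed unnamed. Cluster 6 was monocyte-like, cluster 8 macrophage-like, and cluster 7 mixed markers of lymphocytes and plasma cells.

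The main dendritic cell groups took similar shares in both libraries. Clusters 2 and 3 together held 39.2% of WT cells (95% binomial interval 36.9 to 41.5) and 36.4% of MARCH1 KO cells (31.9 to 41.1). Clusters 1 and 4 together held 39.6% and 37.1%. Leading genes of several single clusters differed between the libraries, so single shares were also taken after clustering without genes 1.5-fold apart. Cluster 3 then held 18.4% of WT and 13.6% of MARCH1 KO cells, and cluster 5 held 11.8% and 18.6%. The sort and the cell filter also set these shares.

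**Figure D1:**
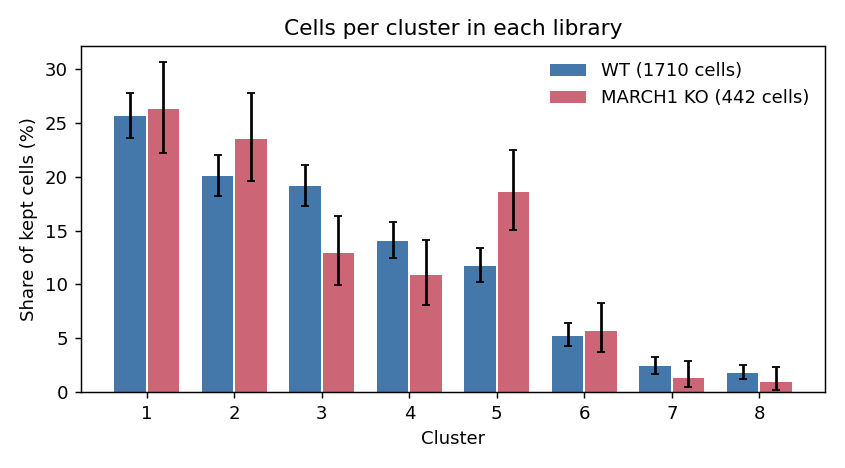
Share of kept cells (%) in each of 8 clusters, WT (1710 cells) and MARCH1 KO (442 cells), with exact 95% binomial intervals that cover counting error only. The largest gap outside the intervals is in cluster 5, at 11.8% in WT and 18.6% in MARCH1 KO.

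Over all kept cells, MARCH1 KO had more RNA of the MHC class II chains that present antigen to CD4 T cells. H2-Ab1 (chromosome 17, 34257689 to 34269419) stood at 511 CPM in WT and 982 CPM in MARCH1 KO, 1.92-fold higher (1.86 to 1.99). H2-Aa was 1.64-fold higher (1.60 to 1.68) and H2-Eb1 1.63-fold (1.60 to 1.67). Cd74, the class II chaperone, differed less, at 1.10-fold. The median log2 ratio of the 12 measured members of the MHC class II list was 0.29, above 100% of matched random lists. The 15 members of the MHC class I list had a median of -0.02, and among them Nlrc5, an activator of class I genes, stood at 54.3 and 82.1 CPM. Nlrc5 lies on chromosome 8 as March1 does (from 94434356), and linkage was not separated for it.

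The other genes with the highest ratios included Rnaset2a, a lysosomal ribonuclease, at 112 and 270 CPM (log2 ratio 1.20), Ass1, an enzyme of arginine synthesis, at 39.2 and 95.3 CPM (1.10), Lad1 (1.08), Gem (1.06), Krtcap3 (1.03), the heat shock gene Hspa1b (1.00), Bloc1s1 (0.99), Mbnl2 (0.93) and the deoxyribonuclease gene Dnase1l3 (0.91). Rnaset2a, Rnaset2b (1.09) and Hspa1b share sequence with near-identical copies, so their counts are uncertain. The lowest ratios included those of Pkib (-1.13), Large (-1.02), S100a10 (-0.95), Cdkn2a (-0.94), Aldh1a2, the enzyme that makes retinoic acid (-0.91), Selm (-0.89), Ehd1 (-0.87), Csrp1 (-0.86), Mir155hg, the host gene of miR-155 (-0.82), Asah1 (-0.81) and Rac2 (-0.79). Lad1 and Csrp1 lie within 20 Mb of Ptprc, whose alleles mark the chimeras' donors, and Large within 20 Mb of March1, so strain variants linked to these loci were not separated from the genotype for these genes. Asah1 lies outside that window but on chromosome 8 as March1 does (from 41340197), and linkage was not separated for it either. Hspa1b lies near H2-Ab1 on chromosome 17 (from 34956436), and a variant shared by them was not tested. Aldh1a2 was at 142 CPM in WT and 71.0 CPM in MARCH1 KO.

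Chemokines that attract CCR4-bearing T cells were lower in MARCH1 KO. Ccl17 stood at 1044 CPM in WT and 683 CPM in MARCH1 KO (0.654-fold, 0.632 to 0.676) and Ccl22 at 2055 and 1417 CPM (0.690-fold, 0.673 to 0.706). Reweighted to the WT mix of clusters, their log2 ratios moved from -0.61 to -0.33 and from -0.53 to -0.30. Both genes lie on chromosome 8 as March1 does (from 94810453 and 94745590), and linkage was not separated for them. Il12b, the p40 subunit of interleukin-12 and interleukin-23, was higher, at 149 and 227 CPM (1.53-fold, 1.43 to 1.63). Of its 1386 MARCH1 KO UMIs, 782 lay in the 57 cells of cluster 3, which it leads, and it was lower in clusters 2 (285 and 234 CPM) and 5 (370 and 247 CPM). Among co-stimulatory genes, Icosl was higher (log2 ratio 0.59), Cd86 lower (-0.40), and Cd40 (0.21) and Cd80 (-0.24) less apart. Tnfsf4, which encodes OX40 ligand, had 18 and 7 UMIs, too few to compare. Ccr7 (-0.08), Zbtb46 (-0.09) and Ptprc (0.03) were near equal.

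Within cluster 1, with 438 WT and 116 MARCH1 KO cells, the class II difference was larger. H2-Ab1 was at 614 and 1534 CPM (log2 ratio 1.31, ratio interval 2.37 to 2.64), H2-Aa 1.98-fold and H2-Eb1 1.98-fold higher, and H2-DMb1, a subunit of the class II peptide exchange factor, 2.61-fold (2.01 to 3.39). The list median was 0.49, with 6 of 13 members at least 1.5-fold higher. H2-Ab1 did not rest on single cells there (1.25 without the top cells). Ccl22 was at 1338 and 546 CPM (0.408-fold, 0.381 to 0.437) and Ccl17 at 540 and 276 CPM (0.510-fold, 0.462 to 0.563). Other high ratios were those of Lad1 (1.77), Ccnd1, a cell cycle cyclin (94.6 and 287 CPM), Vcam1 (1.31), Rnaset2a (1.21), Ass1 (1.16), Bloc1s1 (1.09) and Rnase6 (1.07). Other low ratios were those of Pkib (-1.60), Cdkn2a (-1.38), Mir155hg (-1.24), Ehd1 (-1.17), S100a10 (-1.05), Aldh1a2 (-0.97) and Tnip3 (-0.86). Icosl stood at 74.2 and 156 CPM and Klf4, a transcription factor of type 2 dendritic cells, at 30.6 and 71.4 CPM. Marker genes of plasmacytoid dendritic cells were higher in cluster 1 as well, at 199 and 367 summed CPM (median log2 ratio 0.74), and over all kept cells, at 179 and 263 summed CPM (0.52). These medians rest on 5 of 11 markers. Siglech and Cox6a2 were near absent in cluster 1 (0.473 and 0.158 CPM, both libraries together), so such cells are not shown. Other classes moved in both directions, with medians of 0.32 for cDC2 and -0.29 for Langerhans cell markers in cluster 1. Monocyte markers had -0.63 over all kept cells, on 3 of 11 markers, but 0.61 in the pooled clusters 1 and 4, also on 3.

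Within cluster 2, with 343 WT and 104 MARCH1 KO cells, class II RNA was low in both libraries and no difference in H2-Ab1 was detectable, at 74.7 and 69.6 CPM (0.932-fold, 0.753 to 1.15). H2-Aa was close (431 and 447 CPM), H2-Eb1 higher (443 and 542 CPM) and Cd74 lower (2574 and 2149 CPM). The log2 ratio of H2-Ab1 ran from -0.19 to 0.70 over the alternatives, so its direction is open. Lad1 (1.26), Rnaset2a (1.17), Ass1 (1.03) and Hspa1b (1.01) were higher, and S100a10 (-1.40), Selm (-1.35), Asah1 (-1.05), Klrk1 (-0.95), Stat4, a transducer of interleukin-12 signals (-0.93), Ehd1 (-0.92) and Il2ra (-0.86) lower. Lyz2 had the highest ratio (2.54), but 1 MARCH1 KO cell gave most of its UMIs, and without the top cells it was -0.31. The lowest list medians were those of co-stimulation and co-inhibition (-0.29), type I interferon (-0.27), interferon gamma (-0.25) and retinoic acid and regulatory genes (-0.25). The interferon gamma and regulatory lists share Socs1 and Ido1 and had the same median, so these are not separate results. Ccl17 was close, at 245 and 230 CPM, and Ccl22 lower, at 823 and 636 CPM.

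Within cluster 3, with 327 WT and 57 MARCH1 KO cells, H2-Ab1 was at 354 and 669 CPM (1.89-fold, 1.73 to 2.07), but without the top cells its log2 ratio was 0.38 in place of 0.90. Dnase1l3 (1.34), Bloc1s1 (1.15), Ass1 (1.13) and Ccnd1 (1.05) were higher, and Large (-1.56), Kctd14 (-0.98), Asah1 (-0.97), Cdkn2a (-0.96), Gbp2 (-0.87) and Aldh1a2 (-0.87) lower. Ccl22 was at 2541 and 2764 CPM and Ccl17 at 1327 and 1305 CPM, without the difference seen in cluster 1. Clusters 2 and 3 were both high in Irf8, and which of them a cell fell in depended on the clustering.

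Cluster 4 had 48 MARCH1 KO cells, under the minimum of 50, and is given as values only. H2-Ab1 stood at 1064 CPM in WT and 2273 CPM in MARCH1 KO, and H2-Aa at 1722 and 3250 CPM. In cluster 5, of lower quality, H2-Ab1 stood at 379 and 954 CPM and Ccl22 at 1890 and 824 CPM.

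**Figure D2:**
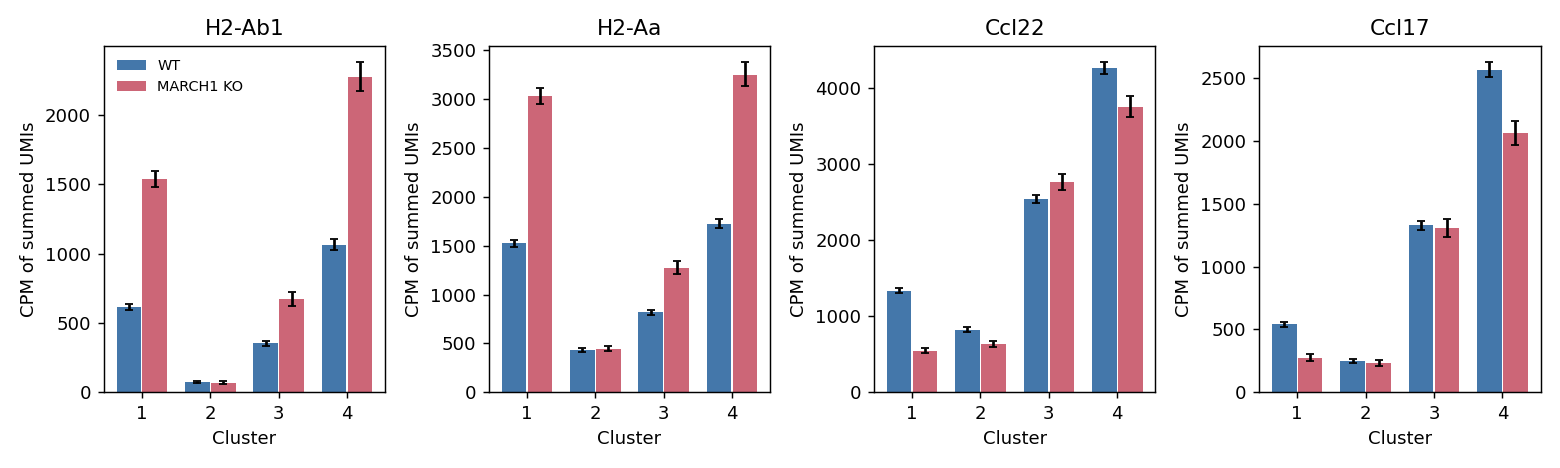
CPM of summed UMIs for H2-Ab1, H2-Aa, Ccl22 and Ccl17 in clusters 1 to 4, WT and MARCH1 KO, with exact 95% Poisson intervals that cover counting error only. H2-Ab1 is higher in MARCH1 KO in cluster 1 (614 and 1534 CPM) and close in cluster 2 (74.7 and 69.6 CPM), and Ccl22 is lower in cluster 1 (1338 and 546 CPM).

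After thinning each cell to 3000 UMIs, H2-Ab1 was seen in 39.6% of WT cells (34.9 to 44.4) and 51.7% of MARCH1 KO cells (42.3 to 61.1) of cluster 1, and Ccl22 in 82.9% (79.0 to 86.4) and 57.8% (48.2 to 66.9). Thinning left out 11 WT and 0 MARCH1 KO cells, and the shares before it were 58.4% and 68.1% for H2-Ab1 and 95.2% and 92.2% for Ccl22. In the monocyte-like cluster 6, with median depths of 3484 and 3316 UMIs, a Ccl22 UMI was seen in 94.6% of thinned WT cells (85.1 to 98.9) and 52.6% of thinned MARCH1 KO cells (28.9 to 75.6), with 34 of 90 and 6 of 25 cells left out by thinning, and RNA from outside the cell was not separated from expression by these cells. Ccl22 stood there at 2267 and 591 CPM.

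The other fixed lists had smaller medians, several of them at the edge of their matched random lists. Over all kept cells the type I interferon list had a median of -0.16 (percentile 0.03), retinoic acid and regulatory genes -0.13 (0.315), chemokines -0.12 (0.95), integrins -0.11 (0.99), the unfolded protein response -0.11 (0.73) and the migratory maturation programme -0.10 (0.91). The co-stimulation list had -0.07, actin cytoskeleton -0.07, interferon gamma -0.06, NF-kB targets -0.06, apoptosis regulators -0.04 and type 2 response genes -0.02. By cluster, the type I interferon list had -0.16, -0.27 and -0.27 in clusters 1, 2 and 3. It went the other way in cluster 4, at 0.24 with 48 MARCH1 KO cells. The pattern recognition list, with 5 of 24 members measured, had 0.20 over all kept cells (percentile 97.2). In cluster 1 it had 0.55, the highest median of any list there. Both medians are the ratio of Tyrobp, which is a signalling adaptor and not a receptor. Fcer1g, also an adaptor, had -0.31 over all kept cells and -0.07 in cluster 1. Over all kept cells, cholesterol synthesis had 0.14 (percentile 99.6), cell cycle 0.13 (97.9), heat shock 0.12 (98.6), endosomes and lysosomes 0.08 (98.3) and immediate early genes 0.08 (97.0). No list but MHC class II and apoptosis regulators had more than 2 members 1.5-fold apart. Psap, a lysosomal sphingolipid activator precursor, stood at 485 and 640 CPM, and Apol7c, a gene induced in mature dendritic cells, at 1603 and 2320 CPM.

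**Figure D3:**
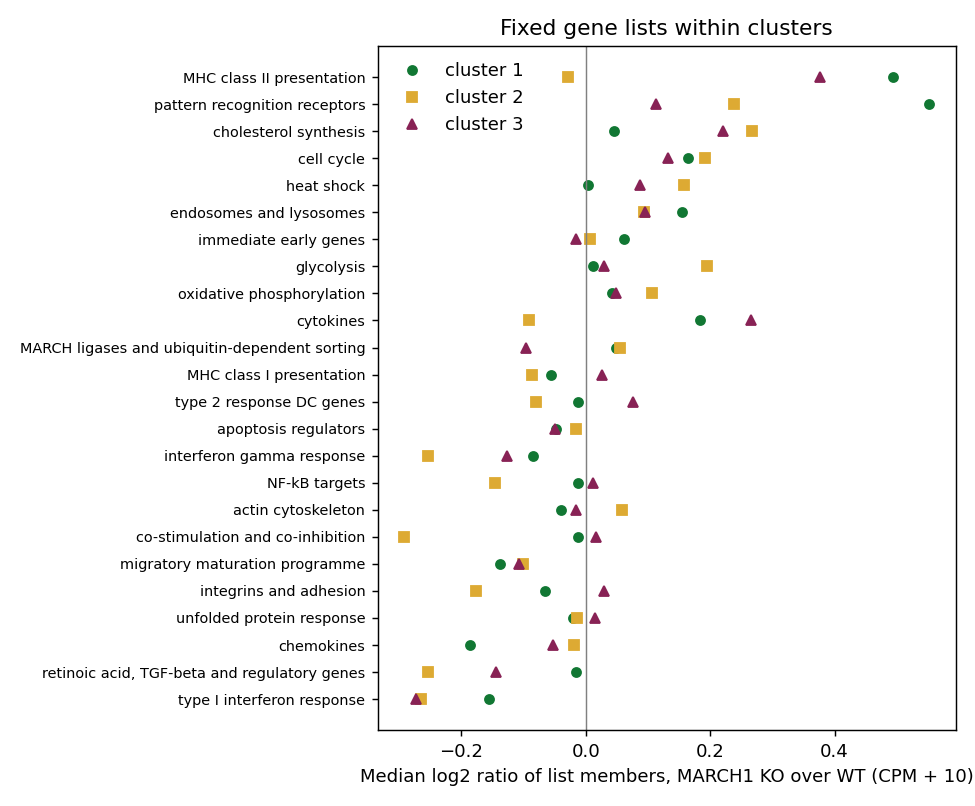
Median log2 ratio of MARCH1 KO to WT (CPM plus 10) for 24 fixed gene lists in clusters 1, 2 and 3, one point per cluster. The MHC class II list lies at 0.49 in cluster 1, -0.03 in cluster 2 and 0.38 in cluster 3.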

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

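The tests in this part were chosen after the results had been seen. Barcodes outside the cell filter were not used in the comparisons but carry signal. In these 731 WT and 239 MARCH1 KO barcodes, H2-Ab1 was lower in MARCH1 KO, at 1011 and 791 CPM (log2 ratio -0.35), opposite to the kept cells, and so were H2-Aa (-0.15) and H2-Eb1 (-0.18). Cd74 also went the other way and by more, at 6953 CPM in WT and 4368 CPM in MARCH1 KO (-0.67). Ccl22 was lower as in the kept cells, at 2215 and 985 CPM (-1.16).

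H2-Ab1 was higher in the MARCH1 KO library. A different mix of these clusters is argued against by the ratio after reweighting to the WT mix (1.09). Reweighting cannot see a different mix of cells within a cluster. In cluster 1 an H2-Ab1 UMI was seen in 58.4% of WT and 68.1% of MARCH1 KO cells. Whether a class II-high subset was larger there in MARCH1 KO was not tested. After thinning, the ratio in cluster 1 was 1.49, so the difference there did not rest on deeper cells weighing more in the sums. Thinning keeps each cell's expected share of H2-Ab1, so it cannot test other effects of depth. More free RNA would reach cluster 2, of similar depth, as well, but the difference was -5.08 CPM there and 920 CPM in cluster 1, above the whole MARCH1 KO level in cluster 2 (69.6 CPM). The MARCH1 genotype remains open as an untested hypothesis, and so does a difference between these libraries, since there is 1 of each. The sort for MHC class II positive cells and a variant near H2-Ab1 were not tested either. Near H2-Ab1 on chromosome 17, Hspa1b (1.00), Aif1 (0.73) and H2-Q4 (0.63) were higher too, while H2-K1 (0.02), H2-D1 (0.03) and Tap1 (-0.02) were close. The 80 genes within 20 Mb of H2-Ab1 had a median absolute log2 ratio of 0.108, against 0.104 for all genes of that floor. The barcodes left out, which go the other way, are a reason for caution.

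Ccl22 was lower in the MARCH1 KO library. A different mix of these clusters is argued against as the whole cause by the ratio within cluster 1 (-1.28), although the mix takes part of the difference over all cells. A different mix of cells within cluster 1 was not tested. Less free RNA stays open, because the values go both ways: Ccl22 was 223 CPM higher in MARCH1 KO in cluster 3, but its difference was -1676 CPM in the monocyte-like cluster 6, whose own expression is not excluded and where Fscn1 was close (3568 and 3806 CPM). Ccl22 lies on chromosome 8, as March1 does. A linked variant that acts alike in every cluster cannot be judged from the ratio of 0.12 in cluster 3. Ccl22 was lower in cluster 2 (823 and 636 CPM), and which of clusters 2 and 3 a cell fell in depended on the clustering. A linked variant, the genotype and a difference between the libraries stay open.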

How the results depend on the processing

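H2-Ab1, H2-Aa, Ccl22 and Ccl17 kept their direction over all kept cells and in cluster 1 under every alternative, while H2-Ab1 in cluster 2 did not. H2-Ab1 ran from 0.78 to 1.10 over all kept cells and Ccl22 from -0.66 to -0.30. In cluster 1, H2-Ab1 ran from 1.15 to 1.49 and Ccl22 from -1.33 to -0.79, with -0.64 where cluster 4 joined it at resolution 0.4. Of all values compared, 3154 were labelled as the same, 342 as shifted and 20 as reversed. These counts depend on the cut-offs of the labels. Not every change of sign was labelled as reversed, such as that of H2-Ab1 in cluster 2 under the strict filter (0.67). With all deposited barcodes and at resolution 0.4, clusters 2 and 3 merged, and at resolution 0.4 clusters 1 and 4 did too, so cluster 3 had no value of its own. It also had none under the strict filter (47 MARCH1 KO cells) or with MARCH1 KO cells placed by WT neighbours (31), for lack of cells. No paired analysis was possible because each genotype has 1 library. Other than these merges, the cause of the shifts below was not tested. Values are log2 ratios, or list medians where a list is named, with the value of the analysis above first.

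With all deposited barcodes, H2-Ab1 went from 0.93 to 0.78 over all kept cells and from 1.31 to 1.21 in cluster 1, and type I interferon response in cluster 1 from -0.16 to 0.0246. The merged clusters 2 and 3 had 0.48 for H2-Ab1, 0.55 for Il12b, 0.12 for MHC class II presentation, -0.00337 for heat shock and -0.0358 for actin cytoskeleton. These are not values of cluster 2, and the pooled clusters 2 and 3 of the kept cells had 0.38, 0.55, 0.13, -0.00987 and -0.0485. Clusters 2 and 3 together held 27.2% of WT and 24.1% of MARCH1 KO cells, and clusters 1 and 4 together 27.9% and 24.1%. With at least 1000 genes and at most 5% mitochondrial UMIs these shares were 46.9% and 48.7%, and 45.6% and 46.3%, H2-Ab1 was 1.42 in cluster 1 and 0.67 in cluster 2, and MHC class II presentation 0.0893 in cluster 2. Without called doublets, H2-Ab1 was 1.15 in cluster 1 and Lyz2 in cluster 2 went from 2.54 to -0.58.

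With each cell weighing the same, H2-Ab1 was 1.10 over all kept cells. With cells thinned to 3000 UMIs, H2-Ab1 was 1.08 over all kept cells, 1.49 in cluster 1, 0.49 in cluster 2 and 0.69 in cluster 3, and Cd86 in cluster 3 went from -0.22 to 0.0525. MHC class II presentation was then 0.20 in cluster 2, cytokines went from 0.26 to -0.000777 in cluster 3, and oxidative phosphorylation from 0.03 to -0.0556 in clusters 1 and 4. Reweighted to the WT mix, H2-Ab1 was 1.09 and MHC class II presentation 0.45 over all kept cells, co-stimulation and co-inhibition went from -0.07 to 0.00456 and actin cytoskeleton from -0.07 to 0.0113.

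At resolution 0.4, H2-Ab1 was 1.16 in the merged clusters 1 and 4 and 0.38 in the merged clusters 2 and 3, where Il12b was 0.55, MHC class II presentation 0.13, heat shock -0.00945 and actin cytoskeleton -0.0491. At resolution 1.5, H2-Ab1 was 0.70 in cluster 2 and 0.72 in cluster 3, Lyz2 went from 1.43 to -1.18 in cluster 3, and MHC class II presentation was 0.12 in cluster 2. With MARCH1 KO cells placed by WT neighbours, H2-Ab1 was 0.63, Il12b 0.0212 and MHC class II presentation 0.0846 in cluster 2, and type I interferon response 0.00999 in cluster 1. Clustered without genes 1.5-fold apart, Lyz2 was -0.51 and actin cytoskeleton -0.00100 in cluster 2. Without the top cell of each library, Lyz2 was -0.31 in cluster 2, and H2-Ab1 was 0.38 and MHC class II presentation 0.12 in cluster 3. With a pseudocount of 1, MHC class II presentation was 0.84 in cluster 1 and 0.46 in cluster 3. With a floor of 50 CPM, cytokines went from 0.18 to -0.0893 in cluster 1.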

Other observations

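A few genes not described above, chosen after their values were seen, differed in the same direction in clusters 1, 2 and 3. Btg2, an early response gene, had log2 ratios of 0.60, 0.81 and 0.81, and Bcl2a1d, a survival gene of the Bcl2 family with near-identical copies, 0.66, 0.57 and 0.73. Tmsb10, an actin-binding peptide, had 0.77, 0.54 and 0.65. Across genes of at least 50 CPM, ratios correlated between clusters 1 and 2 (Pearson 0.549, Spearman 0.446, 1965 genes), 1 and 3 (0.475 and 0.360) and 2 and 3 (0.533 and 0.432). Genes are not independent replicates, and a difference between the libraries would give such values too.

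Further transcripts differed. Jchain, a plasma cell gene, stood at 94.0 CPM in WT and 8.34 CPM in MARCH1 KO over all kept cells, and mostly in cluster 7 (41 WT and 6 MARCH1 KO cells), with 3117 CPM there and 23.5 CPM in the other cells. The ribosomal RNA-overlapping models differed too, Gm42418 at 4879 and 8491 CPM and AY036118 at 228 and 727 CPM. These genes were chosen after their values were seen.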
